A study of Mus musculus with 2 samples.

How the data were processed

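The deposited files are 10x Next GEM 3' v3.1 matrices of UMI counts for 32285 genes, 1 matrix per library, holding the barcodes that the authors' cell calling kept; per the submitters' processing notes the counts were made with Cell Ranger 7.0.0 against mm10. The gene annotation and the setting for intron reads are not given in the sources used here. The matrices hold no GFP, tdTomato or Cre features, so the MADM colour of a cell could not be read. Gene positions and lengths came from GENCODE vM21 on GRCm38, the same build as mm10, and 99.61% of gene identifiers had a length.

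Cells were kept at 1000 UMIs or more, 500 genes or more and less than 10% mitochondrial UMIs. This left out 62 control and 73 KO barcodes by UMIs, 106 and 91 by genes and 21 and 19 by mitochondrial share, and 4265 and 4770 passed. Scrublet, run on each library with an expected rate of 5%, called 107 control cells (2.51%) and 87 KO cells (1.82%) as doublets, which were removed. Kept cells ran from 4098 to 16827 UMIs in control and from 3888 to 19896 in KO between the 5th and 95th percentiles, with medians of 3507 and 3520 genes. Both libraries were log-normalised together, and 2000 variable genes, 30 principal components and 15 neighbours gave 34 Leiden clusters at resolution 1, without correction between libraries. A cluster was named for a cell class only where markers of that class were among its leading genes, and the other clusters kept their number. Some numbered clusters also had class markers among their leading genes, such as clusters 8, 12, 15 and 16. The radial glia-like class (cluster 6) was named from Mfge8 alone, which was higher in the astrocyte-like cluster 13. The excitatory and inhibitory neuron-like classes are clusters 7 and 9, and the OPC-like class is clusters 0, 2 and 17.

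UMIs were summed per cell group and library and divided by the group's total. Groups with at least 100 kept cells in each library were compared, which gave 11. Ratios are KO over control, and the 95% intervals are exact Poisson intervals for levels, exact binomial (Clopper-Pearson) intervals for shares and conditional binomial intervals for ratios of counts below 4. Each covers counting error alone. Intervals of differences between shares were combined from the binomial intervals of the shares. Where alternatives were labelled, list medians and medians over groups had binomial order-statistic intervals over list members or over groups. Those give the spread among members or groups and do not cover counting error. A thinned share of 0 is given with the limit that 3 counts of the total would set. With 1 library per genotype, no test was run on cells, and no gene is called changed. Shares of cells with a given transcript were taken after thinning each cell to 5100 UMIs, which left out 407 control and 468 KO cells below that depth. Sex was called per cell from Xist and Y-linked transcripts.

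Gene lists, list minimum and naming rules were fixed before the data were examined. A list member was measured at 50 UMIs or more over both libraries and was called higher or lower at a ratio of at least 1/0.8 or at most 0.8. List medians were ranked among 10000 random lists of the same size matched on mean expression in 20 bins. Genes were named by rank among those with at least 100 UMIs in the group: the 10 highest and 10 lowest log2 ratios in OPC-like and astrocyte-like cells, and 5 and 5 in the other groups. Sex-linked, mitochondrial and haemoglobin genes and unnamed gene models were left out of the ranking. Across groups, a gene was named if its ratio passed 0.8 or 1/0.8 in the same direction in 11 of 11. List examples are members of at least 100 UMIs among those with the largest absolute log2 ratio.

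A self-test drew Poisson counts from the mean levels and totals of the OPC-like cells and changed 200 of 10161 genes, 50 at each fold size. For fold sizes of 5/4, 1.5, 2 and 4 the median recovered log2 ratio in the OPC-like comparison was 0.30, 0.60, 0.99 and 1.98, and 46%, 100%, 100% and 100% of the 50 genes passed the ratio rule. Of 9961 unchanged genes 5.41% passed it. Lists with no change fell outside the central 95% of random lists in 4.5% of trials, and lists lowered by a log2 of 0.25 were found in 100%. The binomial interval held the true share in 96% of trials. The simulation holds no difference between pools of animals, so these rates are for counting error.

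Alternatives were run for each choice: no cell filter, a stricter filter (2000 UMIs, 1000 genes, 5% mitochondrial), doublets kept, resolution 0.5 and 2, each library clustered separately, cycle, ribosomal, mitochondrial, stress and sex genes left out of the variable genes, and thinning before clustering. For expression they were trimmed mean of M values (TMM) and median-of-ratios scaling, the mean of per-cell levels, totals without mitochondrial and ribosomal genes, clusters weighted to their pooled share, and list minimums of 20 and 200 UMIs. Neurons were also called per cell as excitatory or inhibitory. Other choices were added after results were seen: shares without the granule-marker, Foxg1, 20 and 21 clusters, female and male cells apart, medians over groups without granule markers, and cluster 3 counted as excitatory. Lists matched on gene length were added then too.

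Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. TMM factors came from edgeR 4.0.16 and size factors from DESeq2 1.42.0 in R 4.3.3.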

Results

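Single-cell transcriptomes were collected from the dorsal midbrain of newborn mice (postnatal day 0) that carried MADM-19, a mosaic label (mosaic analysis with double markers) built into chromosome 19, where Pten lies. Nestin-Cre, which is active in neural progenitors, drove the recombination. The design gave 2 groups of 1 pooled library each. Control-MADM pups (26 midbrains, 14000 sorted cells) have wild-type labelled cells. In Pten-MADM pups (24 midbrains, 12000 sorted cells) green GFP-positive cells lack Pten and cells with both colours are heterozygous, in unlabelled heterozygous tissue. Viable GFP-positive cells were sorted, so each share given here is a share of sorted cells. Whether cells with both colours were gated out is not given in the sources used here. The control library held 41351945 UMIs over 4399 barcodes and the Pten-MADM library, called the KO library, 50810022 UMIs over 4909 barcodes. After filtering, 4158 control and 4683 KO cells were kept, with a median of 8718 and 9482 UMIs per cell. With 1 library per group no test between genotypes exists, and each interval printed with a level, share or ratio covers counting error alone. The comparison asks how Pten loss in neural progenitors bears on the cell makeup of the superior colliculus and on expression in its cells.

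Pten (ENSMUSG00000013663; chromosome 19, 32757497 to 32826160, plus strand, GRCm38), the phosphatase that opposes PI3K, was lower in the KO library. Over all kept cells its level was 150 CPM (UMIs per 1000000 UMIs; exact 95% Poisson interval 147 to 154, 5869 UMIs) in control and 116 CPM (113 to 119, 5690 UMIs) in KO. That is a log2 ratio of −0.37, where the median gene stood at −0.17 in the same cells. In oligodendrocyte precursor (OPC)-like cells Pten was at 166 against 112 CPM (log2 −0.57), and in excitatory neuron-like cells at 171 against 118 CPM (−0.54). The log2 ratio was −0.46 in cluster 10 (led by Cdk1 and Nusap1), −0.42 in granule lineage-like cells and −0.39 in cluster 14 (Dll1, Egfr and Ascl1). It lay between −0.21 and −0.09 in astrocyte-like, radial glia-like and inhibitory neuron-like cells and in clusters 3 and 11. Genes of like length and UMI count had medians of −0.03 in OPC-like and −0.16 in excitatory neuron-like cells, and of −0.15 in cluster 3, −0.08 in radial glia-like cells and −0.10 in cluster 11, beside Pten values of −0.15, −0.09 and −0.19 there. In cluster 12, of neurons with granule markers, Pten was at 179 against 187 CPM (0.06). Split by sex in the 9 groups without granule markers, 16 of 18 values were below 0. Pten was higher in KO in male cluster 3 cells (0.32) and in female radial glia-like cells (0.13). The deleted part of the floxed allele is not given in the sources used here, and 3' tags outside it do not check the genotype.

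Cells with markers of cerebellar granule neurons made the largest difference in makeup. Clusters 1, 4, 8, 12, 15 and 25, which expressed Neurod1, Barhl1 or Atoh1, held 10.4% of control cells (exact 95% binomial interval 9.46 to 11.3%) and 40.0% of KO cells (38.6 to 41.4%). These genes alone do not set the clusters apart. Barhl1 was at 357 CPM in cluster 3 and 225 CPM in cluster 7, beside 211 CPM in cluster 1, and Neurod1 was at 272 CPM in cluster 7. Cluster 33, with 21 KO cells and Neurod1 at 254 CPM, was not counted with them. The Atoh1-expressing granule lineage-like cells were 3.66% against 13.7%, the cycling clusters 4 and 15 were 1.37% against 10.4% and 0.770% against 5.27%, and the Nhlh1 and Neurod1 neuroblasts of cluster 8 were 1.78% against 6.45%. Clusters 16, 22 and 31, with the forebrain factor Foxg1, held 0.770% (0.527 to 1.09%) of control and 6.68% (5.99 to 7.44%) of KO cells. Clusters 20 (Gdf10) and 21 (Pax2 and Ptf1a) together held 3.44% against 1.99%. The dissection, with cuts at the borders to the forebrain and to the inferior colliculus, and the GFP sort both bear on these shares.

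These clusters also differed in sex. Of cells that could be called from Xist and Y-linked genes, 0.508% of control granule-marker cells were female (2 female and 392 male cells) against 98.9% in KO (1782 female and 20 male). Clusters 20 and 21 were 0.769% female in control and 100% in KO, and the Foxg1 clusters 50% and 96.0%. In the remaining clusters the female share was 47.7% in control and 58.1% in KO. Among male cells the granule-marker share was 17.4% in control and 2.13% in KO, and among female cells 0.127% and 52.1%. After thinning to 5100 UMIs per cell, Neurod1 was found in 75.1% and 77.3% of granule-marker cells (unthinned 84.0% and 85.6%; median depth 10750 and 11356 UMIs). In OPC-like cells, which should lack it, the values were 0.465% and 1.75% (unthinned 1.03% and 2.07%; median depth 7908 and 7371 UMIs). Atoh1 was found in 13.9% and 13.2% of granule-marker cells (unthinned 22.7% and 26.9%). In astrocyte-like cells (median depth 7992 and 7998 UMIs) 0 of 453 control cells and 0 of 257 KO cells held an Atoh1 UMI, which at 3 counts of the total allows up to 0.662% and 1.17% of cells with a UMI (unthinned 0% and 0.680%).

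**Figure D1:**
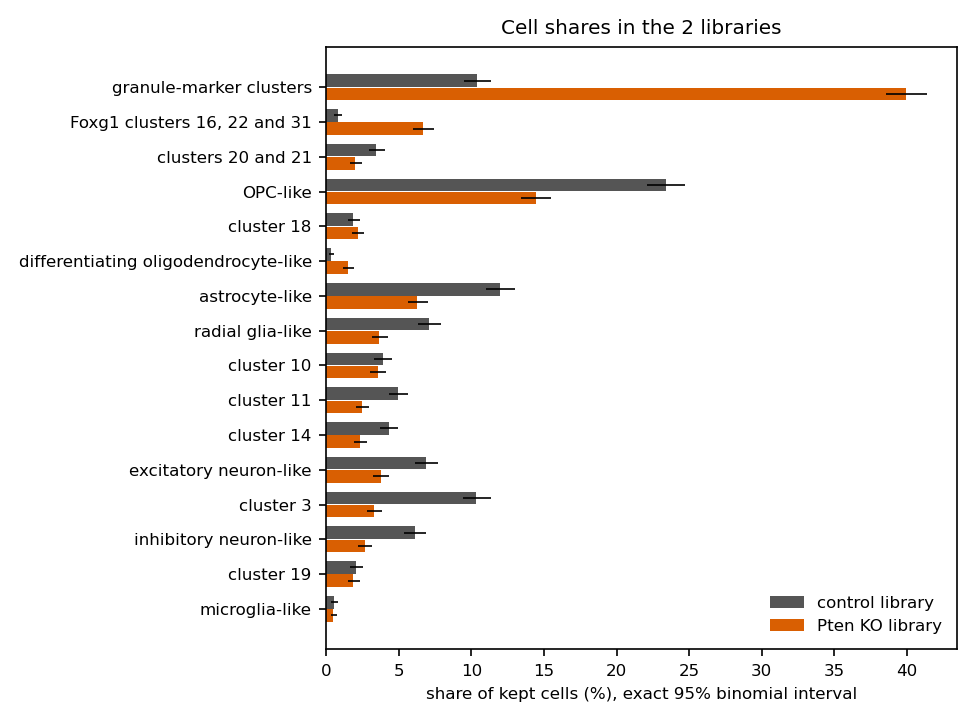
Shares of kept cells (%, horizontal axis) per cell class or cluster in the control (grey) and KO (orange) library, with exact 95% binomial intervals. Granule-marker clusters stand at 10.4% and 40.0%, and OPC-like, astrocyte-like, radial glia-like and neuron-like classes are lower in KO when all kept cells are the denominator.

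**Figure D2:**
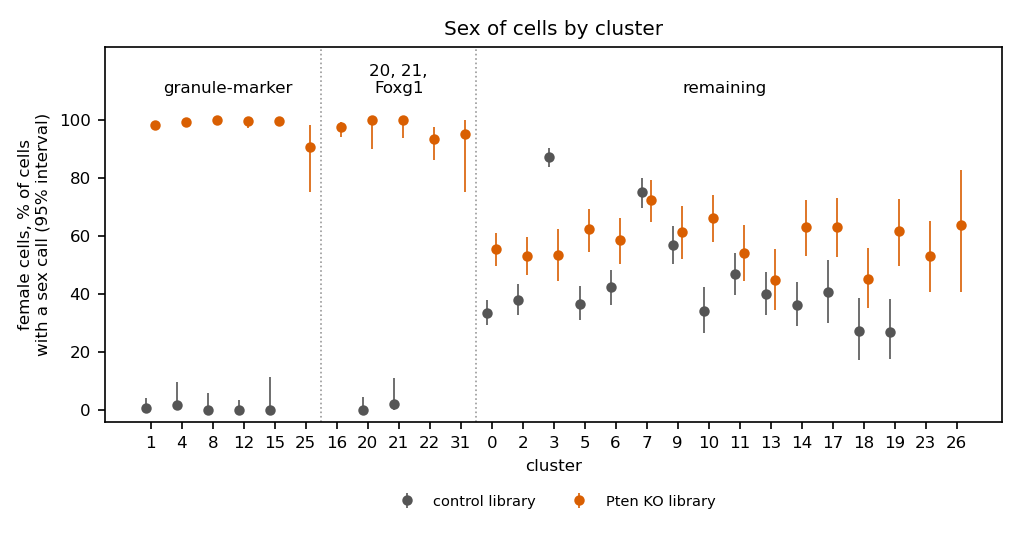
Female cells as a percent of cells with a sex call (vertical axis), per cluster (horizontal axis), in the control (grey) and KO (orange) library, with exact 95% intervals, for clusters of at least 20 called cells. The granule-marker clusters are nearly all male in control and nearly all female in KO.

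Other glia and neurons were compared within the remaining clusters, a denominator chosen after the makeup was seen. These held 85.4% of control and 51.4% of KO cells, so over all kept cells OPC-like cells were 23.4% against 14.4%, astrocyte-like cells 12.0% against 6.28%, and radial glia-like cells 7.10% against 3.65%. Within the remaining clusters OPC-like cells were 27.4% (25.9 to 28.9%) in control and 28.1% (26.3 to 30%) in KO. Astrocyte-like cells were 14% against 12.2% and radial glia-like cells 8.31% against 7.11%, with overlapping intervals. Split by sex, OPC-like cells were 20.4% against 28% of female and 33.4% against 31% of male cells. Microglia-like cells were rare, at 0.529% and 0.470% of all kept cells.

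Differentiating oligodendrocyte-like cells, marked by Plp1, Enpp6, Mbp and Bmp4, were more frequent in the KO library. They were 13 of 1062 oligodendrocyte lineage cells in control (1.22%, 0.653 to 2.08%) and 70 of 847 in KO (8.26%, 6.5 to 10.3%). Female cells gave 0.880% against 8.33% and male cells 1.42% against 8.77%. In the KO library this cluster expressed En1 (36.4 CPM) and En2 (35.3 CPM), which granule-marker cells also expressed, with 1 Foxg1 UMI. In its 13 control cells En1 had 7 UMIs and En2 had 0. Cluster 18, which is counted in this lineage for its Pdgfra (631 CPM) and Olig1 (601 CPM) and was led by cell cycle genes, was 7.25% against 11.9% of the lineage, and cluster 17 (Dll3, Sox10) 8.76% against 11.9%.

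Neurons of the remaining clusters were less frequent in the KO library, at 29.7% against 22.5% for clusters 3, 7, 9 and 19. Cluster 3, which expressed Slc17a6, Zfhx3 and Tfap2d and the thalamic or pretectal markers Tcf7l2 and Lhx2, was 12.1% in control and 6.45% in KO. Excitatory neuron-like cells (cluster 7; Lhx9, Pou4f1 and Ebf2) were 8.05% against 7.28%, and inhibitory neuron-like cells (cluster 9; Gad2, Gata3, Tal1 and Sox14) 7.12% against 5.11%. Inhibitory neuron-like cells were 8.40% against 5.56% of female and 5.78% against 4.85% of male cells, with overlapping intervals in male cells, while excitatory neuron-like cells were 13.1% against 8.97% of female and 3.97% against 4.74% of male cells. Clusters 3, 7, 9 and 19 together held 45.6% of female control and 23.7% of female KO cells, and 16.1% and 19.4% of male cells. Cluster 3 held 22.8% of female control and 5.56% of female KO cells, and 3.03% and 6.72% of male cells. In the control library 87.3% of called cluster 3 cells were female.

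The excitatory share of named neurons had overlapping intervals in the pooled clusters 7 and 9, but depended on the clusters counted and on sex. Excitatory neuron-like cells were 286 of 539 named neurons in control (53.1%, 48.8 to 57.3%) and 175 of 298 in KO (58.7%, 52.9 to 64.4%), a difference of 5.66 points (−1.56 to 12.8). With cluster 3 counted as excitatory, a choice made after the clusters were seen, the shares were 73.9% and 72.8%. Cluster 16, with Dlx1, Dlx2, Gad1 and Gad2, is a Foxg1 cluster and was left out of the shares in this paragraph. It held 14 of 267 cells of clusters 9 and 16 in control (5.24%) and 198 of 321 in KO (61.7%). Counting it as inhibitory would lower the excitatory share more in KO than in control. Cells were also called singly after thinning, over clusters 3, 7, 9 and 19. Of those with either Slc17a6 or GABA genes but not both, 68.9% (65.2 to 72.3%) and 63.9% (58.6 to 69.0%) had Slc17a6, with overlapping intervals. That direction is opposite to clusters 7 and 9 and the same as with cluster 3 counted, so it cannot be credited to calling single cells. Of clusters 3, 7 and 9, clusters 3 and 7 were 81.0% against 72.3% in female and 54.8% against 70.3% in male cells, with intervals apart in both sexes.

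**Figure D3:**
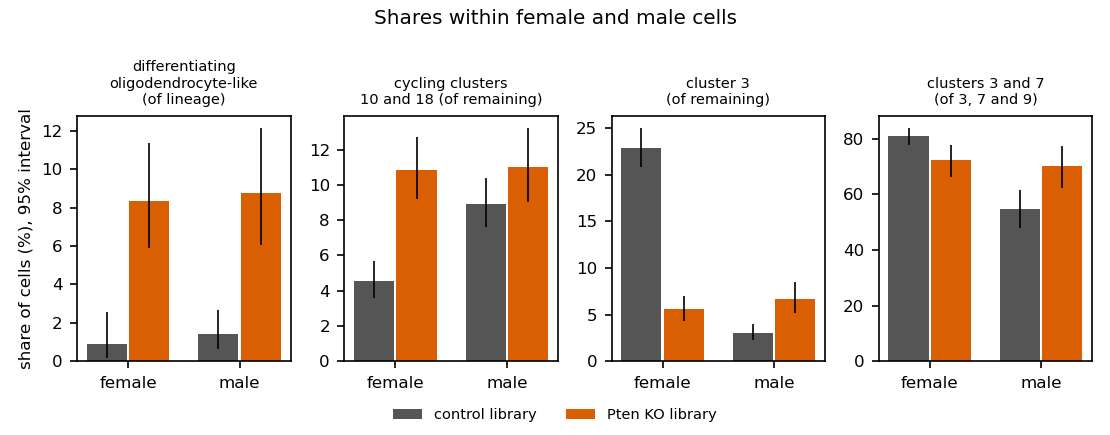
Shares of cells (%, vertical axis) among female and male cells of the control (grey) and KO (orange) library, with exact 95% intervals, for differentiating oligodendrocyte-like cells, cycling clusters 10 and 18, cluster 3, and clusters 3 and 7. The oligodendrocyte share is higher in KO in both sexes (0.880% to 8.33% and 1.42% to 8.77%), while cluster 3 is lower in female cells and higher in male cells.

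Cycling cells were more frequent in the KO library. Clusters 4, 10, 15 and 18, led by Cdk1, Nusap1, Cenpf and histone genes, held 7.86% (7.06 to 8.73%) of control and 21.4% (20.2 to 22.6%) of KO cells. The cycling granule-marker clusters 4 and 15 made up 20.6% and 39.2% of granule-marker cells, and cluster 12, with Nefm, Nefl and Cbln1, 26.9% and 10.5%. Within the remaining clusters, the cycling clusters 10 and 18 were 6.70% (5.90 to 7.57%) against 11.1% (9.83 to 12.4%), and 4.55% against 10.9% of female and 8.93% against 11% of male cells. The Mki67 or Top2a transcript was found in 15.4% of thinned control and 35.7% of thinned KO cells (unthinned 17.7% and 38.4%), a difference of 31.3 points among female and −0.557 points among male cells. In OPC-like cells it was in 12.5% and 17.4% (unthinned 16% and 21.8%), and in astrocyte-like cells in 6.18% and 10.9% (unthinned 9.66% and 15.7%). The neurons of clusters 3, 7 and 9 gave 1.16% and 4.37% (unthinned 2.27% and 5.74%, median depth 8146 and 9492 UMIs), which was also higher in KO. Whether this is background or cycling cells within these clusters was not tested. Over both libraries Mki67 was at 8.5 CPM in cluster 7, beside 1.6 CPM in cluster 3 and 1.9 CPM in cluster 9. Among male cells the cycling share was 10.6% and 11.2%, against 4.57% and 24.7% among female cells.

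Igf1r (ENSMUSG00000005533; chromosome 7, 67952827 to 68233668, plus strand, GRCm38), a growth factor receptor upstream of PI3K, was lower in KO in each of the 11 cell groups with at least 100 cells per library. Of 3412 genes with at least 100 UMIs in each group, it was the 1 gene at a ratio of at most 0.8 in all 11, and no gene was at 1/0.8 or above in all 11. Its level over all kept cells was 170 CPM (166 to 174) in control and 120 CPM (117 to 123) in KO (log2 −0.50). In OPC-like cells it was 148 against 107 CPM (−0.47), in astrocyte-like cells 143 against 93.6 CPM (−0.61), and in cluster 11 (Veph1 and Mia) 179 against 96.0 CPM (−0.90). The median over groups was −0.58, from −0.90 to −0.35. Split by sex, 18 of 18 values were below 0 and 15 were at a ratio of at most 0.8. When each cell was weighted equally, no gene met the rule in all 11 groups, with the Igf1r median at −0.63. With median-of-ratios scaling, Rnaseh2c was at 1/0.8 or above in all 11. Against 200 genes of like length and UMI count, Igf1r was lower by a median of −0.43.

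FOXO targets, which AKT activity represses, had a median log2 ratio below 0 in 11 of 11 groups, with a median of −0.19 and a range of −0.29 to −0.05, and it was below the median gene of the group in 10. Split by sex, 15 of 18 values were below the median gene. In the remaining clusters 0 of 20 members were higher and 4 were lower (median −0.21), at percentile 0.05 among 10000 random lists matched on UMI count, while 2 of 11 groups were in the lowest 2.5%. Among lists matched on length as well, the percentile was 0.03 in this pool, 8.69 in cluster 10 and 56.7 in cluster 3. Among the members, Erbb3, a neuregulin receptor, was at 5.09 against 2.69 CPM (log2 −0.92), the cyclin gene Ccng2 at 26.6 against 18.6 CPM (−0.52), Cited2 (−0.47) and the PI3K inhibitor gene Pik3ip1 at 26.1 against 19.0 CPM (−0.46). In OPC-like cells 6 of 20 members were lower, among them Erbb3 (18.4 against 9.14 CPM) and Cdkn1b, an inhibitor of the cell cycle (88.8 against 68.3 CPM). Radial glia-like cells had 2 of 18 members higher and 7 lower (median −0.29, percentile 0.05). Components of the PI3K, AKT and mTOR pathway had medians below the median gene in 7 of 11 groups (median −0.08, range −0.19 to 0.07), and in the remaining clusters 1 of 31 was higher and 2 were lower (percentile 55.8).

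Genes of cholesterol synthesis were higher in several KO groups. The list's median was above 0 in 10 of 11 groups and in the highest 2.5% of random lists in 7, with a median of 0.15, and 13 of 18 values split by sex were above 0. Cluster 3 had the largest shift, with 20 of 24 members higher (median 0.67; 0.72 in female and 0.23 in male cells): Msmo1, a sterol oxidase, was at 52.9 against 143 CPM (1.43) and Hmgcs1, which makes HMG-CoA, at 242 against 443 CPM (0.87). In cluster 10, 15 of 24 were higher (0.38; 0.02 in female and 0.57 in male cells), with Hmgcs1 at 215 against 339 CPM, and in excitatory neuron-like cells 8 of 21 (0.26), with Msmo1 at 34.1 against 69.3 CPM. In OPC-like cells the median was 0.00, with 1 of 24 higher, and over the remaining clusters 2 of 24 were higher (0.11, percentile 99.98). Fatty acid synthesis genes were higher in cluster 3 (8 of 11, median 0.58) and had a median of 0.09 over groups. Over the remaining clusters 2 of 13 were higher and 1 was lower (0.10). Cluster 3 cells had a median UMI count 1.23 times that of control in the KO library, and the ratio was 1.17 in inhibitory and 1.08 in excitatory neuron-like cells, beside 1.09 over all kept cells. In excitatory neuron-like cells it was 1.16 among female and 0.964 among male cells. The ratio was 0.932 in OPC-like and 0.883 in radial glia-like cells.

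Glycolysis genes were higher in excitatory neuron-like cells, where 8 of 12 members were higher and 1 lower (median 0.51, percentile 100). The median was 0.77 in female and 0.01 in male cells of this cluster, and radial glia and Notch genes were higher there as well (11 of 12, 0.76; 1.36 in female and 0.50 in male cells). Over the 11 groups the median was 0.08 and in the remaining clusters 4 of 18 were higher (0.11). Targets of ATF4, which drives amino acid synthesis, had a median of −0.20 over groups and were lowest in cluster 12, where 2 of 14 were higher and 10 lower (−0.46). In cluster 10, 9 of 19 were lower (−0.32), while over the remaining clusters 2 of 25 were higher and 1 was lower (−0.01; 0.14 in female and −0.04 in male cells). Hypoxia targets had a median of 0.09 over groups (remaining clusters 4 of 15 higher, 2 lower; 0.20 in female and −0.04 in male cells). The unfolded protein response list had 0.07 (1 of 18 higher; 0.15 in female and −0.03 in male cells), p53 targets −0.06 (3 of 18 higher, 1 lower), and lysosomal genes −0.10 (0 of 27 higher, 3 lower), with the lysosomal list at percentile 25.6 in the remaining clusters and in the lowest 2.5% in 1 of 11 groups.

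Transcripts for respiration were higher in the KO library. The oxidative phosphorylation list had a median above 0 in 11 of 11 groups (median 0.17, range 0.07 to 0.40) and in 18 of 18 values split by sex, with 50 of 76 members higher in cluster 3, 41 of 76 in cluster 10, 38 of 76 in excitatory neuron-like and 1 of 76 in OPC-like cells. In the remaining clusters 16 of 76 were higher (0.25), among them Uqcrq at 347 against 458 CPM and Atp5e at 573 against 756 CPM. Mitochondrially encoded genes were also above 0 in 11 of 11 groups (median 0.36), with 10 of 13 higher in the remaining clusters. There mt-Nd1 was at 741 against 1079 CPM and mt-Co3 at 1458 against 2067 CPM, and the median mitochondrial share per cell was 1.09% against 1.5%. Cytosolic ribosomal protein genes had a median of 0.14 over groups, above 0 in 9 and below 0 in 2. In the remaining clusters 15 of 81 were higher (0.20), with Rpl12 at 456 against 669 CPM (0.55) and Rpl23a at 432 against 628 CPM (0.54). They were highest in cluster 14 (55 of 81 higher, 0.37) and lower in cluster 12 (13 of 80 lower, −0.18). Matched on gene length as well as UMI count, random lists had a median of 0.07 beside the oxidative phosphorylation 0.25 in the remaining clusters. For this list they had 0.17 beside 0.40 in cluster 3, 0.13 beside 0.34 in cluster 10 and 0.09 beside 0.32 in excitatory neuron-like cells. Beside the ribosomal 0.20 they had 0.16, and in cluster 3 the ribosomal 0.14 was below their 0.18. Ribosome biogenesis genes had a median of −0.01 over groups and were in the highest 2.5% in 4 of 11; in the remaining clusters 4 of 29 were higher and 1 was lower (0.07, percentile 99.9; 0.20 in female and −0.02 in male cells). Translation factors had 0.06 over groups, and in the remaining clusters 0 of 27 were higher or lower.

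**Figure D4:**
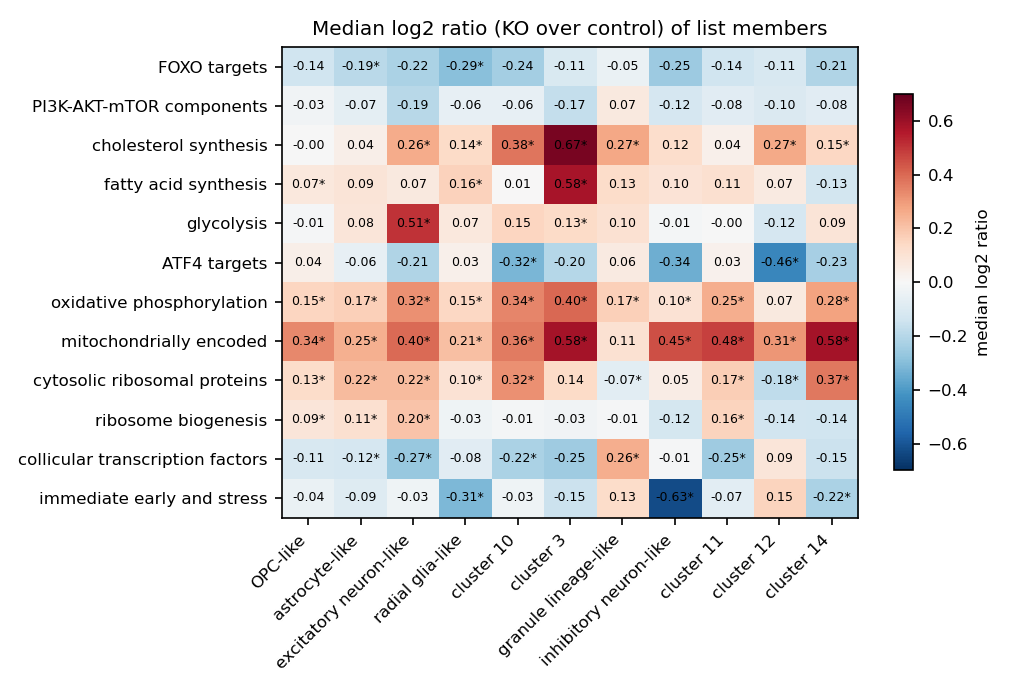
Median log2 ratio (KO over control, colour and printed value) of the measured members of 12 gene lists (vertical) in the 11 cell groups of at least 100 cells per library (horizontal). An asterisk marks the highest or lowest 2.5% of 10000 random lists matched on UMI count; FOXO target medians are below 0 and oxidative phosphorylation medians above 0 in 11 of 11 groups.

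Genes that mark collicular neuron types were lower over the remaining clusters of the KO library, more so in female (median −0.47) than in male cells (−0.10, beside a median gene of −0.07). In the remaining clusters 0 of 43 collicular transcription factor and subtype genes were higher and 18 were lower (median −0.25, percentile 0). The retinal and tectal neuron factor Pou4f2 was at 8.68 against 3.80 CPM (log2 −1.19) and Lhx9 at 161 against 90.3 CPM (−0.84), beside the lower share of neurons in this denominator. Within excitatory neuron-like cells 13 of 35 were lower and 5 higher (−0.27), with Pou4f2 at 31.9 against 10.8 CPM (−1.56) and Irx2 at 64.5 against 26.2 CPM (−1.30). Irx2 was also lower in cluster 3 (141 against 48.4 CPM) and in inhibitory neuron-like cells (56.5 against 19.5 CPM). The list was in the lowest 2.5% of random lists in 4 of 11 groups and in the highest 2.5% in granule lineage-like cells (0.26), and 17 of 18 values split by sex were below the median gene. Matched on length as well, its percentile was 0.245 in excitatory neuron-like cells, 10.5 in cluster 3 and 54.1 in inhibitory neuron-like cells. Markers of thalamic or pretectal neurons were lower as well (0 of 6 higher and 3 lower in the remaining clusters, −0.38), as were those of excitatory neurons (1 of 11 higher and 6 lower, −0.34).

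Neuropeptide and calcium-binding protein genes differed in both directions within excitatory neuron-like cells. Nts, which encodes neurotensin, was at 27.4 against 513 CPM (log2 4.23) and Cartpt at 2.59 against 54.6 CPM (4.39), while 4 of 10 members were higher and 3 lower (median −0.02). In male cells Nts had 74 UMIs in control and 251 in KO, and in female cells 0 and 652. Over the remaining clusters 8 of 19 members of the neuropeptide list were higher and 5 lower (median 0.21; −0.22 in female and 0.51 in male cells), and over groups the median was 0.00. Tac1, which encodes substance P, was lower in inhibitory neuron-like cells (98.9 against 18.4 CPM, −2.43). Pan-neuronal markers had a median of 0.20 over groups (−0.16 to 0.67) and were in the highest 2.5% of random lists in 7 of 11, among them radial glia-like cells (4 of 7 higher, 0.37) and cluster 3 (6 of 10 higher and 2 lower, 0.37). Immature neuron genes had 0.16 (−0.17 to 0.21) and were in the highest 2.5% in 5 of 11. Over the remaining clusters 1 of 10 pan-neuronal genes was higher, and 2 of 17 immature neuron genes were higher and 3 lower. Synaptic (−0.04 over groups; 3 of 34 higher in the remaining clusters) and cytoskeletal genes (0.05; 1 of 26 higher) had opposite signs in the sexes over the remaining clusters, at −0.19 in female and 0.12 in male cells, and at −0.35 and 0.38. Immature neuron genes did too, at −0.24 and 0.15.

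Oligodendrocyte lineage genes were higher over the remaining clusters (9 of 16 higher, 0 lower, median 0.38), led by Enpp6 at 1.27 against 16.2 CPM (log2 3.67), Plp1 at 9.18 against 39.1 CPM (2.09) and Bmp4 at 3.35 against 11.6 CPM (1.79). These 3 genes also named the differentiating oligodendrocyte-like cells, whose share was higher in KO, so their values are not separate from that share. In KO, Enpp6 had 361 UMIs in those cells and 2 in OPC-like cells. Within OPC-like cells the same list had a median of −0.03, and S phase and G2 and M phase lists were higher (14 of 38 and 19 of 38 members; medians 0.26 and 0.32). The G2 and M phase median was −0.23 in female OPC-like cells and the S phase median 0.00 in male ones. Over the remaining clusters 10 of 39 S phase genes were higher and 1 lower (0.15; 0.60 in female and −0.21 in male cells, and −0.12 with clusters weighted to pooled share), and 41 of 49 G2 and M phase genes were higher (0.56; 0.95 in female and 0.34 in male cells). Radial glia and Notch genes had 0 of 21 higher and 4 lower (−0.18; 0.11 in female and −0.33 in male cells). Astrocyte maturation genes had 2 of 23 higher and 5 lower (−0.08; 0.13 in female and −0.24 in male cells), and turned to 0.01 with clusters weighted to pooled share and to 0.02 with the mean of per-cell levels. Immediate early and stress genes stood at −0.07 over groups (4 of 24 higher and 3 lower in the remaining clusters), and at −0.63 in inhibitory neuron-like cells (9 of 14 lower). The haemoglobin list was higher over the remaining clusters (4 of 4, 3.03) and in OPC-like cells (2.11), and lower in excitatory neuron-like (−5.45) and radial glia-like cells (−4.26). Sex-linked genes had a median of −0.40 in the remaining clusters.

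In OPC-like cells (972 control and 676 KO cells), the genes with the highest ratios included Prc1, Top2a, Nusap1 and Brca1 of the cell cycle. Prc1, a protein of the mitotic spindle, was at 6.76 against 20.2 CPM (log2 1.58), Top2a at 22.8 against 42.1 CPM (0.89), and the orphan receptor genes Nr4a2 and Nr4a3 at 13.9 against 31.2 CPM (1.17) and 31.3 against 60.3 CPM (0.95). The immediate early list had a median of −0.04 there, with 4 of 22 members higher and 5 lower. Bche (1.24), Jph1 (1.10), Nrp2 (1.04), Brca1 (1.03), Egr4 (1.01) and Nusap1 (0.97) completed the 10 highest. Lower in KO were Trnp1 at 10.8 against 3.24 CPM (−1.73), the phosphatase gene Dusp26 at 26.5 against 11.2 CPM (−1.24) and the muscarinic receptor gene Chrm3 at 104 against 48.5 CPM (−1.10). Wdr45 (−1.30), Ckmt1 (−1.25), the retinoic acid receptor gene Rarg (−1.18), Col5a3 (−1.06), Nrbp2 (−1.06), Epm2a (−1.05) and C77080 (−1.04) were the other 7 of the 10 lowest. C77080 had the opposite sign in female cells (0.73).

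In astrocyte-like cells (497 and 294), Krt19, a keratin gene, was at 15.8 against 58.2 CPM (log2 1.89), the ephrin receptor gene Epha3 at 9.31 against 27.3 CPM (1.55) and Igfbp3, which binds insulin-like growth factors, at 10.3 against 24.9 CPM (1.28). Nol4l (1.33), Rbfox1 (1.24), Egfem1 (1.03), Adamtsl1 (1.03), Pole3 (1.02), Pak3 (1.01) and Cab39l (1.00) were also among the 10 highest. Epha7, another ephrin receptor gene, was lower, at 21.7 against 7.23 CPM (−1.59), as were Ypel3 at 35.1 against 14.5 CPM (−1.28), the RNA-binding protein gene Igf2bp2 at 27 against 12.5 CPM (−1.11) and Ndnf at 19.1 against 8.84 CPM (−1.11). Nsun6 (−1.17), Hist1h2ap (−1.04), Tcirg1 (−1.02), Rassf10 (−1.01), Gigyf1 (−1.01) and Cyba (−0.98) followed. Epha3 was at 182 CPM in control granule-marker cells, and Hist1h2ap turned to 0.72 when the libraries were clustered separately.

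In excitatory neuron-like cells (286 and 175), Nts and Cartpt were followed by Abca4 at 4.45 against 81.9 CPM (log2 4.20), Esm1 at 7.78 against 135 CPM (4.11) and the centromere gene Cenpa at 5.56 against 52.3 CPM (3.23). Lowest were Nwd2 at 48.2 against 2.27 CPM (−4.40), Gng8 at 37.8 against 3.98 CPM (−3.25), the cell cycle inhibitor gene Cdkn1a at 34.8 against 3.98 CPM (−3.13), C77080 (−1.89; 2.00 with libraries clustered separately) and Hist1h1c (−1.72). In cluster 3 (430 and 155) Sncg (1.49), Msmo1 (1.43), the neurofilament gene Nefl (1.40), Mrpl55 (1.40) and Cks1b (1.29; −0.01 in male cells) were highest, and Chrm2 (−1.99), Ier5l (−1.86), Srp68 (−1.81) and Usp40 (−1.77) were low. Adamts2 had 127 UMIs there in control and 1 in KO, a ratio of 0.018 (0.000451 to 0.102). The median gene was at −0.12 in cluster 3 and −0.06 in excitatory neuron-like cells.

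In inhibitory neuron-like cells (253 and 123), the sulfotransferase gene Hs6st3 was at 81.8 against 280 CPM (log2 1.78), Cdkn1c, another inhibitor of the cell cycle, at 216 against 448 CPM (1.05) and the synaptotagmin gene Syt4 at 249 against 499 CPM (1.00), with Alk (1.42) and Lgals7 (1.22). Beside Tac1, Gpc5 (−2.69), Adcy8 (−2.09), the midbrain factor Irx1 at 75.3 against 18.4 CPM (−2.04) and Ier2 (−1.99) were lowest. In radial glia-like cells (295 and 171) Rtl4 (1.73), Ano3 (1.62), the netrin receptor gene Unc5c (1.40), Gabrb1 (28.2 against 67.2 CPM) and Ccdc141 (1.24) were highest, and Efnb3 (−1.56), Acvr2b (−1.30), Zfp579 (−1.16), Spock2 (−1.14) and Tnfaip6 (−1.07) lowest. Ano3 had the opposite sign in male cells (−1.64), and Unc5c was at 1092 CPM in control granule-marker cells.

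In cluster 10, led by Cdk1 and Nusap1 (161 and 165), Scrg1 (log2 1.55), Hopx (1.13), Stmn2 (1.08), Tubb6 (1.05) and Hddc3 (1.03) were highest, and Fhl1 (−1.42), Unc5d at 128 against 48.1 CPM (−1.41), Hhip (−1.23), Foxb1 (−1.22) and Rad54l (−1.21) lowest. In cluster 11 (206 and 116) the netrin receptor gene Dcc was at 35.9 against 149 CPM (2.06), with Lhfpl3 (1.49), Kcnh7 (1.38), Slco1c1 (1.19) and Olig1 (1.12), and Sgcz (−1.45), Car10 (−1.34), Birc2 (−1.22), Pcdh19 (−1.21) and Zfp622 (−1.18) were lowest. In cluster 14 (4.28% and 2.31% of kept cells) the neuregulin gene Nrg1 was at 30.6 against 141 CPM (2.21), with Tubb3 (1.58), Selenom (1.55), Nyap2 (1.48) and Mt2 (1.40), and Snhg16 (−1.72), Ralyl (−1.52), Mycn at 76.7 against 28.9 CPM (−1.41), Parp8 (−1.33) and Pdgfd (−1.32) were lowest. Dcc, Nrg1, Stmn2 and Tubb3 were abundant in control granule-marker cells, at 3099, 1442, 2284 and 907 CPM. The median gene was at −0.11 in clusters 10 and 14.

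Among granule lineage-like cells (152 and 640), Clstn2 had 1 UMI in control and 127 in KO, a ratio of 29.8 (5.26 to 1187), and Opcml (log2 3.62), Eif3j2 (2.42), Timp3 (2.41) and Airn (2.40) were also highest. The growth factor gene Pdgfa was at 37.4 against 6.48 CPM (−2.53), with Itih5 (−2.35), Dqx1 (−1.86), Ypel3 (−1.79) and Dach2 (−1.78). In the postmitotic neurons of cluster 12 (116 and 196), Synpr (2.45), Syn2 (2.12), the calcium channel gene Cacna1e (1.98), Ier3 (1.78) and Ebf1 at 95.3 against 301 CPM (1.66) were highest, and Cbln2 at 115 against 9.56 CPM (−3.59), C77080 (−2.74), Dach2 (−2.33), Kirrel3 (−2.31) and Rorb (−2.21) lowest. Both comparisons set male control cells against female KO cells, as given with the sex calls.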

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

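The tests of explanations given here were chosen after the results were seen, and the differences were not tested, because each genotype has 1 library.

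Shares in which female and male cells go in opposite directions between the libraries stood out. For granule-marker clusters the KO minus control difference was 51.93 points among female cells and −15.3 points among male cells. For clusters 20 (Gdf10) and 21 (Pax2 and Ptf1a) it was 2.595 and −5.736 points. For cluster 3 (Slc17a6, Zfhx3 and Tfap2d) within the remaining clusters it was −17.26 and 3.684 points, and for clusters 3 and 7 among clusters 3, 7 and 9 it was −8.71 and 15.48 points. Sex is not part of the design, and the difference between libraries was not tested for any of these shares.

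The granule-marker share of the KO library (40.0% against 10.4%) was weighed against 3 explanations. A Pten effect shared by the pooled animals of both sexes does not by itself account for the share, since the male difference was −15.3 points. Sex goes with library in these clusters, so a Pten effect beside a difference in the pooled tissue cannot be told apart. Free RNA of granule cells is argued against by Neurod1, which in OPC-like cells of the KO library reached 0.7328% of its level over all kept cells. There Barhl1 reached 0.8761%, Zic1 1.864% and Atoh1 0%. Cbln1 went the other way, at 11% from 16 UMIs, and was at 11.21% in control OPC-like cells. Tissue outside the midbrain from animals of 1 sex could account for the share, since 98.89% of called granule-marker cells in the KO library were female, and 392 of 394 in the control library were male. Which animals gave the tissue is not in the files.

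The differentiating oligodendrocyte-like share of the KO library (8.26% against 1.22% of the lineage) was higher in both sexes. Animals of 1 sex are argued against by the smaller of the female and male differences, 7.35 points. The depth gap between libraries is argued against by the difference after thinning before clustering, 7.837 points. Loss of Pten in the sorted cells and a difference between the pools in age or dissection cannot be told apart, because the number of libraries per group is 1.

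Lower Igf1r and FOXO target levels in the KO library were weighed in the same way. A trend of the ratio with gene length is argued against for Igf1r over all groups, where it differed by a median of −0.43 from its 200 nearest genes by length and UMI count. In the 5 groups whose ratio falls with length, its percentile among those genes ran from 0 in cluster 11 to 7.5 in cluster 3. By percentile in those groups, the measure used for the FOXO list, the trend is not excluded for Igf1r. For the FOXO list the trend and lower targets cannot be told apart in the 5 groups whose ratio falls with length, where its median percentile among lists matched on length and UMI count was 9.5. Animals of 1 sex are argued against for Igf1r by 18 of 18 values below 0 over both sexes of the 9 groups without granule markers. Igf1r was picked for its low ratio in these same cells, so these values are not independent of that choice. Loss of Pten in the sorted cells and other differences between the pools cannot be told apart for Igf1r and the FOXO targets, with 1 as the number of libraries per group, and replicate libraries of each genotype would be needed to decide.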

How the results depend on the processing

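The splits by sex, the values without the granule-marker, Foxg1, 20 and 21 clusters or without groups of granule markers, and cluster 3 counted as excitatory were chosen after the results were seen; the other settings were planned. For the main results 198 values were computed under alternatives. Of these, 168 lay within the 95% interval of the main value, 22 lay outside it and 8 turned the sign of a value whose interval excluded 0. Of 5887 others the counts were 5433, 425 and 29. For list medians and medians over groups, that interval is the spread among list members or cell groups, not counting error. The interval of the excitatory share spans 0, so its −1.04 with cluster 3 counted as excitatory lies within it. Cells kept their class in 74.5% (resolution 0.5) to 98.9% (resolution 2) of cases. Differences are KO minus control in points, and the cause was not tested for any change. Class shares here are of all cells kept in the setting, or of those of 1 sex, and the excitatory share is of neurons. Values without the granule-marker, Foxg1, 20 and 21 clusters are of the remaining clusters. Thinning before clustering gave 31.7 for granule-marker clusters, −6.94 for astrocyte-like cells and 15.5 for cycling clusters. Astrocyte-like cells gave −7.06 with the stricter cell filter, −7.29 at resolution 0.5, −7.32 with libraries clustered separately and −7.07 with cycle, ribosomal, mitochondrial, stress and sex genes left out. Excitatory neuron-like cells gave −4.50 with libraries clustered separately. The excitatory share per cell after thinning, over clusters 3, 7, 9 and 19, was −4.94. Among female cells the values were 51.93 for granule-marker clusters, −4.51 for radial glia-like, −9.64 for excitatory and −6.26 for inhibitory neuron-like cells, 20.2 for cycling clusters and 31.3 for cells with a Mki67 or Top2a UMI. Among male cells they were −15.3 for granule-marker clusters, 4.46 for OPC-like, 0.121 for astrocyte-like, 0.0849 for radial glia-like, 1.55 for excitatory and 0.279 for inhibitory neuron-like cells, 0.588 for cycling clusters and −0.557 for Mki67 or Top2a. These male values include the lower granule-marker share in the denominator. Within the remaining clusters the male differences were −2.4 for OPC-like, −3.35 for astrocyte-like and −1.83 for radial glia-like cells. They were 0.768 for excitatory and −0.930 for inhibitory neuron-like cells. With both sexes together and without the granule-marker, Foxg1, 20 and 21 clusters, the values were 0.743 for OPC-like, −1.77 for astrocyte-like, −1.20 for radial glia-like, −0.775 for excitatory and −2.01 for inhibitory neuron-like cells, 4.36 for cycling clusters and 8.24 for Mki67 or Top2a. List medians under median of ratios over all kept cells were 0.009 (PI3K, AKT and mTOR) and 0.02 (fatty acid synthesis). With clusters weighted to pooled share, they were 0.15 (fatty acid synthesis), −0.008 (translation factors), −0.039 (G2 and M phase) and 0.018 (astrocyte maturation) over all kept cells. In granule-marker clusters they were −0.042 (ribosomal proteins), −0.12 (G2 and M phase) and 0.12 (synapse), and in the remaining clusters −0.12 (S phase) and 0.008 (astrocyte maturation). With the mean of per-cell levels they were −0.024 (ribosomal proteins, inhibitory neuron-like), −0.004 (G2 and M phase, radial glia-like) and 0.023 (astrocyte maturation, remaining clusters), and after thinning 0.04 (synapse, excitatory neuron-like). In male cells they were −0.039 (translation factors, astrocyte-like), −0.001 (S phase, OPC-like), −0.21 (S phase, remaining clusters), −0.14 (G2 and M phase, radial glia-like), −0.026 (unfolded protein response, remaining clusters), 0.069 (cytoskeleton, excitatory neuron-like) and 0.027 (synapse, excitatory neuron-like). In female cells they were −0.23 (G2 and M phase, OPC-like) and 0.13 (astrocyte maturation, remaining clusters). Among named genes, C77080 was at 0.73 in female OPC-like cells and at 2.00 in excitatory neuron-like cells with libraries clustered separately. Hist1h2ap was at 0.72 in astrocyte-like cells with libraries clustered separately, Ano3 at −1.64 in male radial glia-like cells and Cks1b at −0.009 in male cluster 3 cells. No value exists where clustering gave no such class: radial glia-like cells in 6 settings, inhibitory neuron-like cells and the excitatory share in 2, and differentiating oligodendrocyte-like cells in 1. No paired analysis was possible, because each genotype has 1 pooled library.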

Other observations

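The comparisons given here were chosen after the cell makeup was seen. The rarer cell types of the sort were present in both libraries. Without GFP or tdTomato features in the matrices, whether these cells carried the MADM label could not be read. Microglia-like cells (C1qa, C1qb and Trem2) numbered 22 and 22, mural-like cells (Rgs5, Vtn and Kcnj8) 16 and 22, fibroblast-like cells (Col1a2, Col3a1 and Dcn) 14 and 16, endothelial-like cells (Cldn5, Flt1 and Kdr) 10 and 14, and ependymal-like cells (Tmem212 and Rsph1) 11 and 23. Cluster 26, led by Rbp4, Spp2, Sspo and Spdef, had 12 control and 26 KO cells. Endothelial-like cells also held haemoglobin transcripts and had a median of 37181 UMIs. Cluster 33, with a median of 1320 UMIs and Tsix among its leading genes, had 21 cells in KO and 0 in control.

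Regional genes overlapped between OPC-like and granule-marker cells. OPC-like cells expressed En1 at 56.1 CPM in control and 35.8 CPM in KO, En2 at 22 and 19.2 CPM and Irx2 at 66.7 and 62.6 CPM. Granule-marker cells expressed En1 at 21.9 and 12.6 CPM, En2 at 50.8 and 49.4 CPM, Irx2 at 40.7 and 32.5 CPM and Barhl1 at 187 and 186 CPM, with 0 Foxg1 UMIs. The Foxg1 clusters had Foxg1 at 237 and 285 CPM, and En1 at 0 and 1.21 CPM. Among them cluster 16 (Dlx1, Dlx2, Dlx5 and Arx) was 0.337% of control and 4.23% of KO cells, and cluster 22 (Neurod6, Tbr1 and Emx1) 0.313% and 2.03%. Within differentiating oligodendrocyte-like cells Plp1 was at 597 and 864 CPM, Enpp6 at 248 and 424 CPM, and Mbp at 583 and 985 CPM.

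The log2 ratio followed gene length in some groups. The rank correlation with gene span was −0.316 in cluster 10, −0.314 in cluster 3, −0.205 in cluster 14, −0.199 in cluster 11 and −0.199 in excitatory neuron-like cells, 0.125 in cluster 12 and between −0.019 and 0.0923 in the other 5 groups. In cluster 3 the shortest 25% of genes had a median of 0.09 and the longest 25% had −0.26. Among lists matched on length and UMI count, the remaining-cluster medians were at percentile 100 for oxidative phosphorylation, 96.7 for ribosomal proteins, 98.7 for glycolysis and 0 for collicular transcription factors.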
